A study of Xenopus tropicalis with 18 samples.

How the data were processed

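RNA was measured in coccyx and hypochord of wild-type Xenopus tropicalis tadpoles at stages 56, 58, 61 and 65, while the series' design text speaks of 3 stages. Per the labels' protocols, the tissues were frozen in embedding medium, cut out by laser capture microdissection and extracted with a kit for very small samples, and the complementary DNA was made by template switching and amplified by PCR before sequencing. Such libraries carry no molecular identifiers, so PCR copies of one molecule count as separate reads, and intervals and floors cover counting error only. The submitters' processing notes name FastQC, cutadapt 1.8.1 and HTSeq 0.13.5. The aligner, the genome build and the annotation are not given in the sources used here. How regions were chosen beyond the tissue is not given in the labels.

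Each deposited file holds whole-number counts per gene of one library, not normalized, with the unit taken per the file headers and checked against the values. No file held summary lines such as reads without a gene, and no pair of libraries held identical values. Of the listed genes, 4035 had 0 counts in the 12 libraries of replicates 1 and 2, and 4706 had 0 counts in the 6 libraries of replicate 3. A gene with overlapping neighbours or near-identical copies has an uncertain count, since the counting settings are not given in the sources used here. Total counts ran from 1918822 to 7271829 in replicates 1 and 2 and from 10418992 to 17125833 in replicate 3. CPM of single genes given by identifier are TMM-normalised, so that a total is multiplied by its library's factor (0.596 to 1.39), and on this scale a floor of 3 counts is 0.463 to 1.20 CPM. Ratios of pooled counts and the floor over a group use the total counts without these factors, as do the CPM ranges that group genes by abundance in the closing section.

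Samples were grouped by the tissue and stage in their labels, and replicate numbers were taken from the labels. The design fixed before the data were examined had one fit of 16 libraries from stages 56, 61 and 65. It could not be made, because the identifiers of the replicate 3 tables, which run from 2 to 21459 without a gap, could not be matched to those of the other tables. Under the shared identifiers the values were unrelated (Spearman's rho 0.0079), while the last 37 lines of both tables had a rho of 0.97, higher than in any of 10000 random pairs of stretches (highest 0.695). The same test was therefore run on the 10 libraries of replicates 1 and 2 from those stages, and replicate 3 was tested apart. The leave-out of replicate 3 is thus the test itself and not an alternative.

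Of the identifiers in replicates 1 and 2, 0 were found in the RefSeq gene table given with the data, and the files do not pair identifiers with names. The planned marker lists, key genes and tests of gene lists were therefore not run. The rule for named genes, fixed before the data were examined, took the largest rises and falls in log2 fold change among genes with an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap of groups, or for the tissue mean the same direction at the 3 stages. It also asked for a gene symbol. Without symbols, 2 genes in each direction are given by identifier for the mean tissue difference alone.

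Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr by group, robust quasi-likelihood fits with one coefficient for each of 6 groups, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. The fit had 4 residual degrees of freedom, 12328 genes and a common biological coefficient of variation of 0.559. The stage 56 groups had 1 library each and were assumed to vary like the other groups. The filter took its number of libraries from the smallest group, so a gene could enter this fit through 1 library. Standard errors of log2 fold changes are approximate, from the fold change and its test statistic. The fit of the 4 pairs of stages 61 and 65 with the pair as a block had 3 residual degrees of freedom, and the fit of replicate 3, with stage and tissue as terms, had 2.

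The labels give the tissues the same replicate numbers without saying what they mark. Between tissues the deviations of replicates 1 and 2 correlated with r = 0.34 at stage 61 and 0.19 at stage 65 across 12328 genes. The numbers were therefore taken to pair the tissue samples within a stage, which is an assumption. With 2 replicates, exchanging the numbers in a tissue only turns the sign of r, so these values cannot establish the pairing. Where samples come from the same animals a block is needed, and blocked values are given where they move a count. Between stages 61 and 65 the deviations had r = -0.11 in coccyx and 0.02 in hypochord, so the numbers were not taken to pair stages.

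Genes detected at equal depth are the expected number of genes with at least 1 count when 1918822 counts, the smallest total, are drawn from a library without replacement. Tissue labels were permuted within stage and table over all 1152 arrangements, two-sided, and swapped within the 9 pairs over all 512 swaps, a test added after seeing the data. Log2 CPM for correlations used a prior count of 2. Alternatives were DESeq2's size factors in edgeR, no filter on low counts, at least 10 counts in at least 8 libraries, DESeq2 1.42.0, limma 3.58.1 voom with sample weights, the block, stage 58 counted as replicate 2 of stage 56, and leaving out each library. The fits of stages 61 and 65 alone, of one tissue effect and of replicate 3 were chosen after seeing the data. Detection, permutations and figures used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.

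The tests were tested on simulated data with 200 changed genes. For the unblocked tissue comparison at stage 61, with 11617 genes, 15% of 4-fold and 87% of 16-fold changes were recovered with 3 false calls. For the paired comparison of stages 61 and 65, with 10879 genes, 55% and 93% were recovered with 5 false calls. The changed genes were drawn from those above 4 CPM. The simulated counts had the trended dispersion and no pair effect. Recovery of scarcer genes, and false calls under pair effects or a spread particular to a gene, were thus not tested.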

Results

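The urostyle is the rod of bone that ends the vertebral column of frogs, and it forms at metamorphosis from a dorsal coccyx and a ventral hypochord. To describe gene expression in both parts while the tadpole tail is lost, RNA of wild-type Xenopus tropicalis was measured in coccyx and hypochord tissue cut from frozen sections by laser capture. The 18 libraries, 9 of each tissue, came from stages 56, 58, 61 and 65. Stages 61 and 65 had 3 libraries per tissue, stage 56 had 2 and stage 58 had 1. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

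The 12 libraries of replicates 1 and 2 listed 19921 genes and held 1918822 to 7271829 counts each. The 6 libraries of replicate 3 listed 21458 genes and held 10418992 to 17125833 counts each. The identifiers of the replicate 3 libraries rose by exactly 1 at each of 21457 steps, and 11315 of them also stood in the other libraries. Over these shared identifiers the mean coccyx log2 CPM of replicate 3 and of the other replicates had a Spearman's rho of 0.0079 across genes, which are not independent replicates. Replicate 3 was therefore compared only within itself. The files do not pair the identifiers with gene names, so genes are described by number, direction and abundance, and 4 are given by identifier.

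The coccyx libraries detected more genes than the hypochord libraries at every stage and in every replicate. At an equal depth of 1918822 counts, 12653 ± 600 genes were detected in coccyx and 9793 ± 1918 in hypochord (SD, n = 9), and coccyx was higher in 9 of 9 pairs of the same stage and replicate. An exact permutation test of the tissue labels within stage and table, two-sided, gave p = 0.00174 (adjusted p = 0.00521 over 3 measures, Benjamini-Hochberg). Swapping the tissues only within pairs, a test added after seeing the data, gave an exact p of 0.00391 (adjusted p = 0.0117). Within replicates 1 and 2 the exact permutation p was 0.0139 (adjusted p = 0.0417) and the exact p of swaps within pairs was 0.0312 (adjusted p = 0.0469), the smallest that 64 swaps allow, with coccyx higher in 6 of 6 pairs. Within replicate 3 the exact permutation p was 0.25, the smallest that 8 arrangements allow, with coccyx higher in 3 of 3 pairs.

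The stage 56 and stage 58 hypochord libraries of replicates 1 and 2 stood apart from all other libraries. At equal depth they detected 6875 and 6611 genes, against 10720 to 11125 in the 4 hypochord libraries of stages 61 and 65 and 12184 to 13098 in the 6 coccyx libraries. The coccyx libraries of stages 56 and 58 detected 12793 and 12835 genes. In replicate 3 the stage 56 hypochord library detected 10175 genes, and the lowest value was that of the stage 61 hypochord library, 8822. The share of counts in the 10 most abundant genes was 17.6% in coccyx and 19.2% in hypochord (exact permutation p = 0.354, adjusted p = 0.354; within pairs p = 0.152, adjusted p = 0.152). The effective number of genes, the exponential of the Shannon entropy of a library's counts, was 1120 ± 390 in coccyx and 828 ± 282 in hypochord (SD, n = 9 per tissue), with coccyx higher in 8 of 9 pairs. It missed the threshold when labels were permuted within stage (exact permutation p = 0.0573, adjusted p = 0.0859) and passed it when they were swapped within pairs (exact p = 0.0117, adjusted p = 0.0176). The stage 61 libraries of replicate 2 had the highest such shares, 31.5% in coccyx and 33.7% in hypochord.

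**Figure D1:**
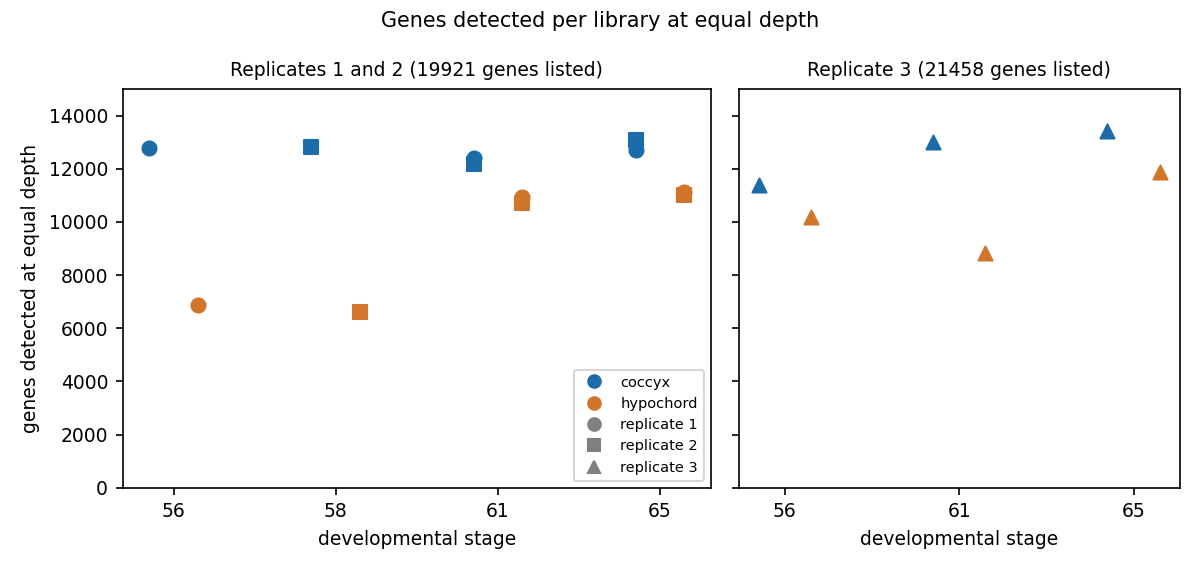
Genes detected in each library at an equal depth of 1918822 counts (vertical axis, number of genes) by developmental stage (horizontal axis), with 1 point per library, the tissue as colour and the replicate as shape, and replicate 3 in its own panel because its table lists other genes. The coccyx point lies above the hypochord point of the same stage and replicate in 9 of 9 pairs, and the stage 56 and 58 hypochord libraries of replicates 1 and 2 lie lowest, at 6875 and 6611 genes.

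Over all 4 stages coccyx profiles kept their rank order more closely than hypochord profiles, and the stage 56 and 58 hypochord libraries carried most of that gap. Across the genes of replicates 1 and 2, coccyx libraries of different stages had a mean Spearman's rho of 0.923 (lowest 0.900, highest 0.946, 13 pairs of libraries), and replicates of one stage had 0.913 and 0.955. Hypochord libraries of different stages had a mean rho of 0.807 (lowest 0.719, highest 0.925, 13 pairs), and replicates of one stage had 0.906 and 0.911. The lowest of these values, 0.719, was that between the stage 56 and stage 58 hypochord libraries. Between stages 61 and 65 alone, 4 pairs of hypochord libraries had rho from 0.884 to 0.925 and 4 pairs of coccyx libraries had 0.916 to 0.944. In replicate 3 the rho between these stages was 0.814 in hypochord and 0.929 in coccyx. At stages 61 and 65, coccyx and hypochord libraries of the same stage had a mean rho of 0.886 (lowest 0.862, highest 0.929, 8 pairs). The highest of these tissue pairs lay within the range of replicates and was that of replicate 2 of stage 61. It lay above the rho between the replicates of stage 61 in coccyx (0.913) and in hypochord (0.906). These are correlations across genes, which are not independent replicates.

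The first comparison asked which genes differed between coccyx and hypochord. With edgeR's quasi-likelihood test on replicates 1 and 2, the mean tissue difference over stages 56, 61 and 65 called 3080 of 12328 genes at an adjusted p under 0.05, of which 2874 were higher in coccyx and 206 were higher in hypochord. The stage 56 hypochord library had no counts for 41.3% of the tested genes and for 67.1% of the called genes. With stages 61 and 65 alone the same model called 445 genes, 413 higher in coccyx and 32 higher in hypochord. One tissue effect over the same 10 libraries called 582 genes, and with stage 58 counted as replicate 2 of stage 56 the mean comparison called 2241, or 664 with the pair as a block. Without replicate 1 of stage 65 coccyx the mean comparison called 1842 genes, and without replicate 2 of stage 65 coccyx it called 1521.

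The genes higher in coccyx included a set with no hypochord counts at all. In replicates 1 and 2, 25 genes had at least 10 counts in each of 6 coccyx libraries and none in 6 hypochord libraries, and 0 genes had the reverse. Of the 142 other arrangements of these libraries within stage, the highest count was 0. At stages 61 and 65 alone there were 40 such coccyx genes and 0 hypochord genes, against a highest count of 1 in 34 other arrangements. In the separate replicate 3 table, 96 genes had at least 10 counts in each of 3 coccyx libraries and none in 3 hypochord libraries, 0 had the reverse, and the highest of 6 other arrangements was 11. Every other arrangement asks for 0 counts in a coccyx library, and coccyx libraries detected more genes throughout. Low counts in the other arrangements and in the reverse can follow from that gap. They do not tell coccyx-only genes from genes missed in the hypochord libraries.

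Among genes past the threshold with a mean log2 CPM of at least 3 and the same direction at the 3 stages, ENSXETG00000032275 and ENSXETG00000030920 had the largest excess in coccyx. ENSXETG00000030920 had 713 counts over 6 coccyx libraries, 4.54 to 49.6 TMM-normalised CPM (as are all CPM of single genes here), and 0 counts in 6 hypochord libraries. It was at least 223-fold higher in coccyx against a floor of 3 counts over the group, by total counts, which covers counting error only. Its edgeR log2 fold change was 9.50 ± 1.41 (SE, adjusted p = 0.00714). With 0 hypochord counts this value depends on the method. It was 8.63 without replicate 1 of stage 61 coccyx and 7.01 with limma voom. ENSXETG00000032275 had 2129 counts in coccyx and 1 in hypochord, a ratio of 2000 with a 95% counting interval of 359 to 79031. Its coccyx counts were uneven, since 1599 of them came from replicate 1 of stage 61 (304 CPM) and 4 from replicate 2 of stage 61 (0.757 CPM), and its edgeR log2 fold change was 9.60 ± 2.39 (SE, adjusted p = 0.0354, range over 18 alternatives 1.31e-06 to 0.154). Without replicate 1 of stage 61 coccyx it was 7.07, and without replicate 2 of stage 65 hypochord, which held the single hypochord count, it was 10.66.

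The largest excess in hypochord under the same rule was that of ENSXETG00000022195 and ENSXETG00000022198. ENSXETG00000022198 had 146 CPM in stage 56 hypochord and 0.521 CPM in stage 56 coccyx. At stage 61 it had 47.0 and 4.19 CPM in hypochord and 1.90 and 1.33 CPM in coccyx, and at stage 65 it had 46.8 and 112 CPM in hypochord and 12.7 and 4.30 CPM in coccyx. In stage 58 hypochord, outside the test, it had 0 counts. Its edgeR log2 fold change of coccyx over hypochord was -5.01 ± 0.86 (SE, adjusted p = 0.00744, range over 19 alternatives 9.09e-11 to 0.241), or -4.14 without replicate 1 of stage 61 hypochord. ENSXETG00000022195 had a log2 fold change of -5.39 ± 1.28 (SE, adjusted p = 0.0252, range over 19 alternatives 4.06e-09 to 0.293), or -4.01 without replicate 1 of stage 61 hypochord. The block by pair ended this call (-5.04, adjusted p = 0.142). It reached 191 CPM in stage 56 hypochord and 264 and 267 CPM in stage 65 hypochord, and 109 and 25.6 CPM in stage 65 coccyx. In stage 61 hypochord it had 196 CPM in replicate 1 but 5.69 in replicate 2, against 0.760 and 3.79 CPM in coccyx. At stage 58, outside the test, it had 1 count in hypochord (0.186 CPM) and 9 in coccyx (1.39 CPM).

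At stage 56, with 1 library per tissue in this fit, 2610 genes were called, 2427 higher in coccyx and 183 higher in hypochord. With the stage 58 libraries counted as replicate 2 of stage 56, 2782 genes were called without a block, and with the pair as a block 182 were called, 165 higher in coccyx and 17 higher in hypochord. The difference in the fit as planned has no replicate check of its own, since the lone libraries were assumed to vary like those of the other groups. Spearman's rho between the tissues at stage 56 was 0.760 in replicate 1 and 0.889 in replicate 3, which could not be joined to this fit. Replicate 3 had 0.811 at stage 61 and 0.892 at stage 65, and the stage 58 pair had 0.765. The wide tissue gap of replicate 1 at stage 56 was thus not seen in replicate 3. Of the called genes, 62.9% had no counts in the stage 56 hypochord library. Without replicate 1 or replicate 2 of stage 65 coccyx, which contribute to the estimate of the spread, 1660 and 1698 genes were called.

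At stages 61 and 65 taken singly, most called genes were higher in coccyx, and their number depended on the model. Without a block, edgeR called 2 genes at stage 61 and 1 at stage 65, each higher in coccyx, with 1292 and 1481 genes at an unadjusted p under 0.05, while DESeq2 called 463 and 502. On data simulated for the unblocked stage 61 test, 15% of 4-fold and 87% of 16-fold changes were recovered among changed genes above 4 CPM. The replicate numbers were taken to pair the tissues, which these data cannot establish. With the pair of stage and replicate as a block, 313 genes were called at stage 61, 286 higher in coccyx and 27 higher in hypochord. At stage 65 the blocked fit called 458 genes, 409 higher in coccyx and 49 higher in hypochord. With stage 58 also counted as replicate 2 of stage 56, the blocked fit called 0 genes at stage 61 and 3 at stage 65, with 680 and 851 at an unadjusted p under 0.05. Without replicate 2 of stage 61 coccyx the unblocked test called 301 genes at stage 61 and 178 at stage 65, and without replicate 1 of stage 61 coccyx it called 177 at stage 65. Leaving out any one of the stage 65 libraries of either tissue gave 0 at both stages, and leaving out either stage 61 hypochord library gave 0 at stage 61 and 3 or 4 at stage 65.

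A fit of the 4 pairs of stages 61 and 65 with one tissue effect, chosen after seeing the data, called 716 of 10959 genes. Of these, 617 were higher in coccyx and 99 were higher in hypochord, and without the block the count was 479, 441 higher in coccyx and 38 higher in hypochord. The strict filter on low counts, at least 10 in at least 8 libraries, asks for them in every library of this fit. Genes missing or scarce in any hypochord library are thus removed by rule. It gave 126 genes, 86 higher in coccyx and 40 higher in hypochord, while DESeq2 called 1342 (1099 and 243) and limma voom 1404 (1115 and 289). The direction varied with abundance: of the called genes with a mean log2 CPM below 3, 243 were higher in coccyx and 2 in hypochord, and of those at 7 or more, 47 were higher in coccyx and 36 in hypochord. The median log2 ratio of coccyx to hypochord over all tested genes was 0.42 below a mean log2 CPM of 3, 0.06 from 3 to 5, -0.04 from 5 to 7 and -0.20 at 7 or more. In this fit ENSXETG00000032275 and ENSXETG00000030920 had log2 fold changes of 9.76 and 9.96 (adjusted p = 0.000943 and 0.00181), ENSXETG00000022198 had -3.31 (adjusted p = 0.0188), and ENSXETG00000022195 had -2.89 and missed the threshold (adjusted p = 0.22). Leaving out the pair of stage 65 replicate 1 gave 369 genes, that of stage 65 replicate 2 gave 408, that of stage 61 replicate 1 gave 470 and that of stage 61 replicate 2 gave 1166, 900 higher in coccyx and 266 higher in hypochord.

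**Figure D2:**
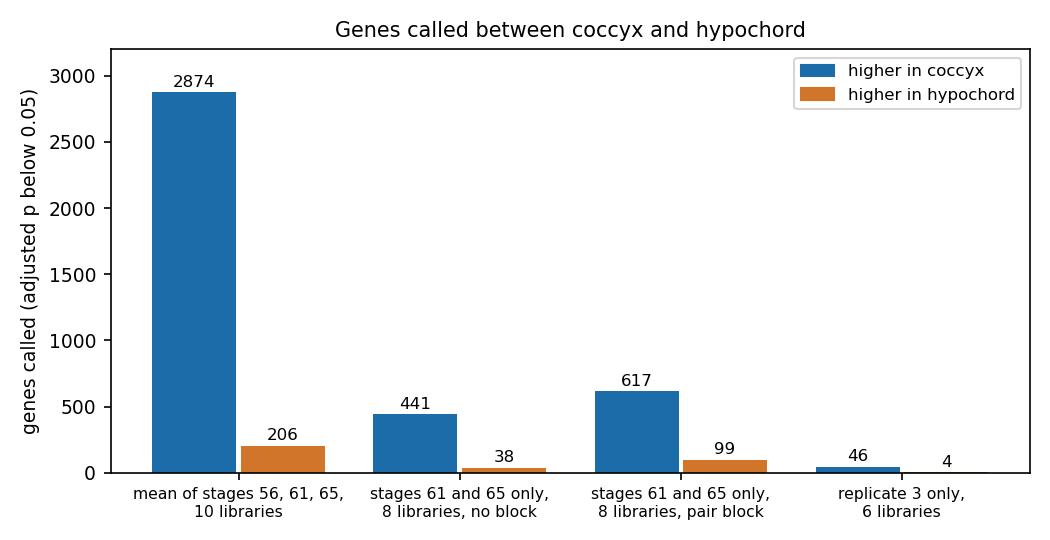
Number of genes called between coccyx and hypochord at an adjusted p under 0.05 (vertical axis) in 4 fits (horizontal axis), split into genes higher in coccyx and genes higher in hypochord. In the first fit and in that of replicate 3 a gene could pass the filter on low counts through a single library. With a filter by tissue, not drawn, replicate 3 called 0 genes. The mean over stages 56, 61 and 65 called 2874 and 206 genes, one tissue effect over stages 61 and 65 alone called 441 and 38 without a block and 617 and 99 with the pair as a block, and replicate 3 alone called 46 and 4.

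In replicate 3 alone, with stage and tissue as terms and 6 libraries, edgeR called 50 of 13930 genes between the tissues, 46 higher in coccyx and 4 higher in hypochord. Each group of stage and tissue held a single library here. A gene could thus pass the filter on low counts through a single library, also one of coccyx. With a filter on low counts by tissue in place of stage and tissue, edgeR called 0 of 11485 genes, with 780 at an unadjusted p under 0.05. This fit had 2 residual degrees of freedom.

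The log2 ratios of coccyx to hypochord correlated more closely between stages 61 and 65 than between other pairs of stages. The raw share of genes with the same direction did not show this, but it has unlike baselines. Over 9461 genes, the log2 ratio of coccyx to hypochord at stage 61 correlated with that at stage 65 with a Pearson's r of 0.64 and a Spearman's rho of 0.40. This was the largest absolute r of the 9 ways to divide the libraries of each stage, the next being 0.40. With 9 ways a share under 0.05 cannot be reached. They also exchange tissue labels only, so they do not compare pairs of stages. Of the 100 genes with the largest absolute log2 ratio at stage 61 among 2677 genes with a mean log2 CPM of at least 5, 85 had the same direction at stage 65, against 62.3% of all such genes. No other pair of stages was counted in this way. Pairs of stages that included stage 56 or 58 had r from 0.26 to 0.35, and stages 56 and 58, with 1 library per tissue each, had r = 0.29. Ratios at stages 61 and 65 rest on more libraries, and the stage 56 and 58 hypochord libraries detected few genes. Both can lower r for the other pairs. The gap in r thus does not show that the tissue differences themselves were more alike at stages 61 and 65. The share of genes with the same direction was 62.1% for stages 61 and 65 and 62.3% for stages 56 and 58. More genes were higher in coccyx at stages 56 and 58 (64.3% and 63.8%) than at stages 61 and 65 (53.3% and 56.1%). That common shift alone gives stages 56 and 58 the higher share, so the shares are not directly comparable. Among the 2677 genes with a mean log2 CPM of at least 5, r was 0.54 for stages 61 and 65 and at most 0.41 for the other pairs, that of stages 58 and 61. Genes are not independent replicates, and these correlations carry no p-value.

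**Figure D3:**
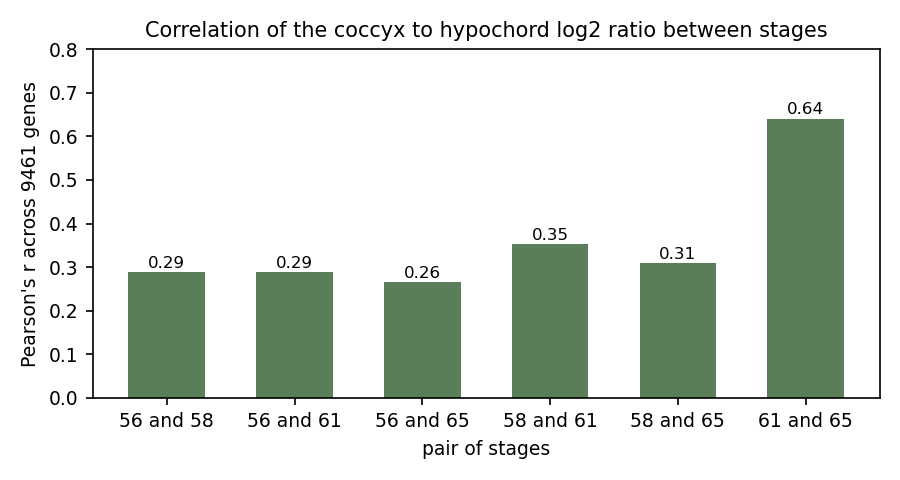
Pearson's r across 9461 genes (vertical axis) of the log2 ratio of coccyx to hypochord between each of 6 pairs of stages (horizontal axis) in replicates 1 and 2. The bar for stages 61 and 65 reaches 0.64, and the other 5 bars lie between 0.26 and 0.35.

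The stage 58 libraries, 1 per tissue, were described by their values and not tested as a stage of their own. They did enter the tests of genes detected and the fits that counted stage 58 as replicate 2 of stage 56. The median log2 ratio of coccyx to hypochord was 1.22 at stage 58 and 0.93 at stage 56, against 0.06 at stage 61 and 0.11 at stage 65. Its SD across genes was 2.64 at stage 58, 2.49 at stage 56, 1.14 at stage 61 and 1.29 at stage 65. Coccyx had the higher value for 63.8% of genes at stage 58 and 56.1% at stage 65.

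The second comparison asked what changed in each tissue over metamorphosis. In hypochord, 3252 genes were called between stages 56 and 61, of which 2683 rose and 569 fell. Between stages 56 and 65, 3582 hypochord genes were called, of which 2757 rose and 825 fell. Both rest on the single stage 56 hypochord library, which had no counts for 53.1% and 48.5% of these genes. With stage 58 counted as replicate 2 of stage 56 the counts were 1690, of which 58 fell, and 1815, of which 139 fell. Adding the replicate number as a block gave 1292 and 1465. Without replicate 2 of stage 65 hypochord the second count was 2383. From stage 61 to 65 edgeR called 0 hypochord genes, with 1081 at an unadjusted p under 0.05, while DESeq2 called 177 and limma voom called 2.

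In coccyx the number of genes past the threshold between stages was small with edgeR and limma voom and larger with DESeq2. Counting stage 58 as replicate 2 of stage 56 left 0 edgeR calls from stage 56 to 61 and 0 from 56 to 65. The counts that follow leave stage 58 out. With edgeR, 2 genes were called between stages 56 and 61 and 2 between stages 56 and 65, each of which rose, with 1281 and 1655 genes at an unadjusted p under 0.05. From stage 61 to 65 edgeR called 0 coccyx genes, with 400 at an unadjusted p under 0.05, while DESeq2 called 100, of which 90 fell, and limma voom called 0. For the change from stage 56 to 61 DESeq2 called 230 coccyx genes, of which 42 fell, and limma voom 1. For the change from stage 56 to 65 DESeq2 called 388, of which 112 fell, and limma voom 18, of which 14 fell. With no filter on low counts edgeR called 41, of which 23 fell. Without replicate 2 of stage 61 hypochord, a library in none of the coccyx groups, edgeR called 50 coccyx genes between stages 56 and 65, of which 36 fell, and 20 between stages 61 and 65, each of which fell.

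The third comparison asked whether the tissues changed differently with stage. The interaction of tissue with stage, 65 against 56, called 1562 genes with edgeR. For 1474 of them the change from stage 56 to 65 was more positive in hypochord than in coccyx, and for 88 it was more positive in coccyx. The stage 56 hypochord library had no counts for 63.7% of the called genes. Limma voom with sample weights called 688 genes, and with the stage 58 libraries counted as a second replicate of stage 56, edgeR called 447, or 0 with the pair as a block, where 2210 genes had an unadjusted p under 0.05. Without replicate 1 or 2 of stage 65 coccyx edgeR called 552 and 639 genes, and without replicate 2 of stage 65 hypochord it called 979.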

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

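The tests of depth, abundant genes, lost molecules and silent genes below were chosen after the result was seen. The interaction of tissue with stage, 65 against 56, called 1562 genes, 1474 of them with a more positive change in hypochord, and is given here because it tests a difference between the tissues' stage effects directly. It called 552 genes without replicate 1 of stage 65 coccyx, 639 without replicate 2 of stage 65 coccyx and 979 without replicate 2 of stage 65 hypochord. With the stage 58 libraries counted as a second replicate of stage 56 it called 447 genes, or 0 with the pair as a block, where 2210 had an unadjusted p under 0.05. It rests on the stage 56 hypochord library, which had no counts for 63.7% of the called genes.

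That library and the stage 58 hypochord library of replicate 2 detected few genes, and 2 technical causes are argued against. At equal depth they reached at most 6875 genes against at least 10720 in the later hypochord libraries (SD 170), so depth does not account for it, and with the 100 most abundant genes left out they reached at most 6835 against 10903 (SD 178), so neither does a few genes taking the counts. Genes at 4 to 16 CPM in the later hypochord libraries were at 0 in 41.0% and 38.4% of 3237 cases. Their summed CPM relative to genes 16 times as abundant was yet 1.09 and 1.21 times the later value. The later libraries ran from 0.869 to 1.15 (SD 0.157). Silent genes with the rest unchanged were predicted to give the share not at 0, 0.590 and 0.616, and the sums lay above it. That share weighs each gene the same, while the sum weighs genes by CPM. The genes were also chosen by their level in the later libraries, which can raise the sum in any other library. These sums therefore do not decide whether silent genes were the whole cause. Loss of RNA molecules before amplification stays open: a sum can be carried by few genes, the median ratio of the genes still detected to their later level was 1.05 and 0.796 (1.25 and 1.11 relative to the more abundant genes, against 0.861 to 1.16 in the later libraries), and coccyx libraries had 1.33 to 2.31 on the summed measure, so other genes being higher would raise it too. Of the 3237 genes, 20.6% were at 0 in both early libraries, against 15.7% if the zeros were independent. Many genes at 0 in one early library were thus detected in the other. The libraries differ in stage, and scarcer genes can be missed in both, so this overlap does not decide between lost molecules and silent genes. A difference between stages stays open and untested, and in replicate 3 the stage 56 hypochord library detected 10175 genes and the stage 61 hypochord library 8822.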

How the results depend on the processing

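Of the 207 alternative counts of called genes, 107 lay within 1.5 times the count they were compared with. None of the 74 alternative fold changes of the 4 genes given by identifier reversed. The weakest was -2.89, that of ENSXETG00000022195 in the paired comparison, against -5.39 in the test as reported. These genes were picked for large fold changes with the same direction at the 3 stages, and the alternatives refit mostly the same libraries. The lack of reversals is thus not a test of robustness. The fits of stages 61 and 65 alone, of one tissue effect, of replicate 3 and of stage 58 with the block were chosen after seeing the data, as was every value of the paired comparison, and the rest were planned. The order of counts below is that of the report: tissue mean, tissue at 56, 61 and 65, coccyx and hypochord between stages, interaction. Unless a cause is named, the cause was not tested. The filter of at least 10 counts in at least 8 libraries is called strict below. In the paired comparison it asks for these counts in every library, so genes scarce in hypochord drop out by rule. DESeq2's size factors in edgeR moved no count beyond 1.5 times.

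With no filter on low counts the tissue called 101 genes at stage 61 and 125 at stage 65, coccyx 16 (61 against 56), 7 (65 against 61) and 41 (65 against 56), and hypochord 51 (65 against 61). The strict filter, which tests fewer genes, called 1917 in the tissue mean, 0 at stage 61, 0 at stage 65, 1 in coccyx (65 against 61) and 126 in the paired comparison (86 higher in coccyx, 40 in hypochord). DESeq2 called 463 genes at stage 61, 502 at stage 65, 230, 100 and 388 in coccyx in the order above, 177 in hypochord (65 against 61) and 1342 in the paired comparison. Limma voom called 0 at stage 61, 1 in coccyx (61 against 56) and 18 (65 against 56), 2 in hypochord (65 against 61), 688 in the interaction and 1404 in the paired comparison.

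With the pair of stage and replicate as a block, the numbers being taken to pair the tissues, the tissue called 313 genes at stage 61 and 458 at stage 65; the block changed no other tissue count beyond 1.5 times (3623 in the mean, 3572 at stage 56, 2217 in the interaction). Between stages the samples share only a number, and with the replicate block coccyx called 0 (61 against 56) and 1 (65 against 61) and hypochord 5 (65 against 61).

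With stage 58 as replicate 2 of stage 56, the tissue called 0 genes at stage 61 and 0 at stage 65, coccyx 0 (61 against 56) and 0 (65 against 56), hypochord 1690 (61 against 56) and 1815 (65 against 56), and the interaction 447. Adding the replicate block gave 664 in the tissue mean, 182, 0 and 3 at stages 56, 61 and 65, 0 and 0 in coccyx against stage 56, 1292, 1 and 1465 in hypochord (61 against 56, 65 against 61, 65 against 56) and 0 in the interaction, where edgeR had 2210 genes at an unadjusted p under 0.05.

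For the tissue mean, stages 61 and 65 alone gave 445, or 716 as pairs with one tissue effect; one tissue effect over the 10 libraries gave 582, and replicate 3 gave 50, or 0 with its filter by tissue. At stage 61, stages 61 and 65 alone gave 1.

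Leaving out each library in turn gave 1521 to 3288 in the tissue mean, 1660 to 2989 at stage 56, 0 to 301 at stage 61 and 0 to 178 at stage 65. Coccyx ran from 0 to 4 (61 against 56), 0 to 20 (65 against 61, highest without replicate 2 of stage 61 hypochord) and 0 to 50 (65 against 56, highest without the same library). Hypochord ran from 2220 to 3391, 0 to 21 (highest without replicate 1 of stage 61 hypochord) and 2383 to 4027, the interaction from 552 to 1867 and the paired comparison from 369 to 1166. Where a stage 56 library was left out, comparisons that need it have no value. Groups left with 1 library were assumed to vary like the others. Tests of gene lists and key genes were not run, and leaving out replicate 3 is the test as reported. Adjusted p rose above 0.05 in 14 of the 74 fold changes, 13 of them in ENSXETG00000032275 and ENSXETG00000022195. Total counts of 1918822 to 7271829 limit the scarce genes most, since a floor of 3 counts is 1.20 TMM-normalised CPM in the smallest library.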

Other observations

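The test of lost molecules at stages 61 and 65 and the counts over other splits of the libraries were set out before their results were seen, and the tests of depth and of the identifiers, the limit to splits that part every pair and the reading of the sum against the share of genes detected after. At stages 61 and 65 the excess of genes higher in coccyx was steepest among scarce genes, with 243 against 2 called genes below a mean log2 CPM of 3 and 47 against 36 at 7 or more. At equal depth the hypochord libraries reached at most 11125 genes against at least 12184 in coccyx (SD 397). Depth thus does not account for the gap in genes detected. The calls were not repeated at equal depth, so depth stays open for the excess among called genes. Genes at 4 to 16 CPM in coccyx kept a summed CPM, relative to genes 16 times as abundant, of 0.902 on average in the 4 hypochord libraries (0.814 to 1.01), against 0.879 to 1.12 in the coccyx libraries (SD 0.104). Loss of RNA molecules in the hypochord captures stays open, because the mean sum lies within the coccyx range. That sum also lies at the share of these genes still detected in hypochord, 0.900. Silent genes with the rest unchanged would give that share if each gene weighed the same. A true difference between the tissues stays open as untested.

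The numbers being taken to pair the tissues, the counts of called genes were set against the other splits within stage that part every pair. For the 3080 genes of the mean tissue comparison the real split is 1 of 16 such splits, too few for a share under 0.05, and the highest other called 1347. Of all 36 splits of the 10 libraries the highest other called 2012 genes and the median was 1020, and each of them kept the stage 56 coccyx and hypochord libraries apart. For the 716 genes of the paired comparison the real split is 1 of 8 that part every pair, and for the 50 genes of replicate 3 it is 1 of 4. The highest other called 0 in both, and these splits are too few as well.

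In the replicate 3 tables, 21457 of 21457 steps between successive identifiers were exactly 1, against 13429 of 19920 in the tables of the other replicates, and values under shared identifiers were unrelated. A running number written in place of the original identifiers is a candidate explanation that goes with this. No biological explanation was tested for it.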
